A study of Hordeum vulgare with 47 samples.

How the data were processed

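Grains of 2 barley lines, LP104 and LP106, were sampled at 8 stages from 0 to 144 hours after imbibition, with 3 biological replicates per line and stage per the labels, and 2 for LP106 at 0 h. Each of the 47 samples was hybridised to a 1-colour array, with total RNA labelled with Cy3 per the labels' protocols. The deposited scanner files hold the intensity of each spot, extracted with Agilent Feature Extraction 11.5.1.1 per the file headers, with a processed signal corrected for background, and flags for spots well above background, saturated spots and outliers. The deposited series matrix holds 33710 probes on what fits a log2 scale, centred so that each probe's median over the arrays is 0. Set against the scanner values, its columns had correlations across probes of 0.895 to 0.991 and slopes of 0.771 to 1.12, and column medians of -0.148 to 0.111. The steps behind that centring and scaling are not given in the sources used here.

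Each array held 62976 spots, 61158 of them non-control spots for 55835 probes. The log2 processed signal minus each array's 75th percentile was used. Outlier spots, 8 to 561 per array, were left out, and spots of a probe were averaged. Of 53258 probes with a usable spot on all arrays, 33879 were tested, those well above background on every array of at least 1 of the 16 groups. No spot was left out for saturation, as 0 non-control spots were saturated. The number of arrays limits the precision.

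Groups were taken from sample titles. The title of one LP104 0 h array gives replicate 3 and its source name another number; the title was followed. A fit with limma 3.58.1 in R 4.3.3, having a mean per group over all 47 arrays, left 31 residual degrees of freedom. Its moderated tests covered LP106 minus LP104 at each stage and on average, each later stage against 0 h, successive stages, and the line by time interaction (F-test). Benjamini-Hochberg adjustment was made within each comparison, with a threshold of 0.05. Exact permutation tests were used for single values; the smallest two-sided p is 0.1 for 3 arrays against 3 and 0.2 for 3 against 2. The design, most alternative settings and the limit on named IDs were fixed before the data were examined; spike-in scaling, the slide row term, the fit on scan day 2 and the scalings of the peak stages were added afterwards.

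The files pair probe IDs with no gene names, and 0 IDs matched the reference table of genes. The 25 gene lists fixed beforehand therefore had 0 matched probes and were not tested. For probes without names the rule allowed at most 2 IDs that rose and 2 that fell. Those named, settled after the files were read, have the largest fitted rise and fall from 0 to 144 h shared by both lines, and the highest and lowest fitted average line difference among probes with 1 sign at all 8 stages. A fold where a probe was not well above background on all or most of a group's arrays is given as a lower bound, taken against the higher of the probe's own value and the lowest signal among probes well above background on each array.

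The arrays lay on 8 slides and were scanned on 4 days, both tested as fixed blocks and, where both groups shared one, within it. Alternatives were quantile, median and spike-in scaling (7 spike-in probes with a mean log2 of at least 6), normexp background with an offset of 50, no filter and a stricter filter, other variance and array weights, fewer groups, blocks, the series matrix, and each array left out. On simulated data with 200 changed probes among 33879, the 24 h line comparison recovered 44.5% of changes of 1 log2 unit and 84.5% of changes of 2. The average line difference recovered 96% of changes of 1, the change from 0 to 144 h 64% and the transition from 2 to 24 h 65.5%. The interaction recovered 23%, with the change set in LP106 at 144 h alone. Simulated noise was normal and independent between probes. Far more probes passed the threshold in the data, which makes the adjustment less strict there, so these shares do not carry over to the data.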

Results

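Gene expression was measured in germinating grains of the barley lines LP104 and LP106, which the series describes as elite breeding lines that differ in stress tolerance. Grains were kept in the dark and sampled at 0, 2, 24, 48, 72, 96, 120 and 144 h after imbibition, the uptake of water that starts germination. There were 3 arrays per line and stage, and 2 for LP106 at 0 h, 47 in all. Probes carry IDs without gene names, so groups of probes are described by when and in which line they changed. Replicate arrays of a group correlated across probes with r between 0.961 and 0.991, and 45 of 47 arrays had their closest match within their own group. The first component of all 33879 probes held 62.7% of the variance, the second 11.8% and the third 6.1%.

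**Figure D1:**
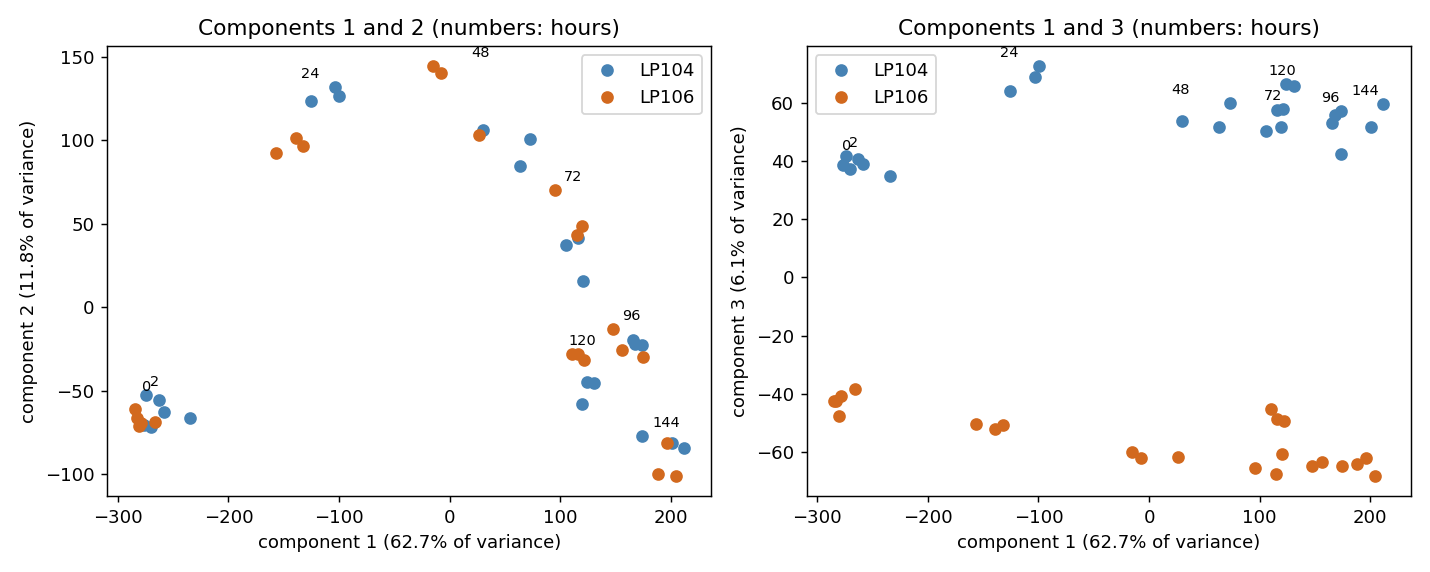
Principal components of the 47 arrays, component 1 against components 2 and 3, with the percent of variance on each axis; each point is 1 array, coloured by line, and numbers give hours after imbibition. Component 1 holds 62.7% of the variance.

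The first comparison asked how expression changed over germination in both lines. Few probes changed in the first 2 h, 1196 higher and 2166 lower than at 0 h. By 24 h 9061 probes were higher and 16295 lower, and by 144 h 11414 were higher and 17550 lower, of which 8344 and 13478 changed at least 2-fold. Between these, 27736 probes differed from 0 h at 48 h, 28204 at 72 h, 28514 at 96 h and 27984 at 120 h. The share of higher calls at 144 h was 39.4% with the 75th percentile, 53.2% with the median, 47.7% with quantiles and 95.7% with spike-ins, and the median of all probes moved from -0.49 to 0.12, -0.11 and 3.11 log2 units. At 24 h these shares were 35.7%, 54.3%, 49% and 98.3%, at 48 h 38.1%, 55%, 49.8% and 98.2%, and at 72 h 39.4%, 56.2%, 49.9% and 96.2%. They were 40%, 56.1%, 49.7% and 95% at 96 h, and 39.3%, 55.7%, 49.9% and 96.5% at 120 h. At 2 h the share was 35.6%, against 49.5% with quantiles and 73.8% with spike-ins. The counts of higher and lower probes are relative to each array's 75th percentile. With no filter on dim probes the count at 144 h was 47099 of 53258 probes tested. With the filter on all 47 arrays it was 14175 of 15936, against 28964 of 33879 in the reported fit. The change from 0 to 2 h fell from 3362 probes to 1779 with median scaling, to 872 with array weights, to 393 with normexp and to 72 with only the groups compared.

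The probe with the largest fitted shared rise, CUST_8953_PI404877155, was at least 1580-fold higher at 144 h than at 0 h (limma adjusted p = 1.08e-18). This is a bound, since at 0 h it was well above background on only 1 of 3 LP104 arrays and 1 of 2 LP106 arrays. It holds for the reported processing only. With normexp the fitted rise was 8.66 log2 units, against 11.15. The largest fitted shared fall, CUST_27_PI402346722, was above background on all 47 arrays. It went from 10.91 ± 0.10 (SD, n = 3) in LP104 and 10.41 ± 0.21 (SD, n = 2) in LP106 at 0 h to -2.67 ± 0.83 and -2.89 ± 0.28 (SD, n = 3 each) at 144 h, a difference of -13.44 (limma adjusted p = 4.28e-30). With spike-in scaling that difference was -9.84.

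Successive stages were compared to find when expression changed most. From 2 to 24 h 9428 probes rose and 16396 fell, and from 24 to 48 h 8348 rose and 12059 fell. Later steps had fewer, with 12795 probes from 48 to 72 h, 8195 from 72 to 96 h and 8176 from 96 to 120 h. The last step, from 120 to 144 h, had 5199 higher and 8059 lower. The step from 2 to 24 h had the most probes in 14 of 15 alternatives. With spike-in scaling the step from 24 to 48 h did, by a narrow margin (22142 against 22114 from 2 to 24 h). Over the alternatives the count ranged from 3814 to 16468 for 48 to 72 h, 2445 to 13022 for 72 to 96 h, 1754 to 13816 for 96 to 120 h and 5077 to 17155 for 120 to 144 h. The share of higher calls from 2 to 24 h was 36.5%, against 56.4% with the median, 49.8% with quantiles and 95.7% with spike-ins, and from 24 to 48 h 40.9%, against 52.7% with the median and 97.7% with spike-ins. With spike-ins it was 77.3%, 67.7%, 69.6% and 73.5% for the later steps in order, against 46%, 49.4%, 44.5% and 39.2%. With slide as a block the step from 96 to 120 h fell to 2933 probes. Within single slides, 1062 probes passed from 48 to 72 h and 10704 from 120 to 144 h, with groups of as few as 1 array, assumed to vary like the others. Within 1 slide 0 probes passed from 0 to 2 h by limma, 3441 having an unadjusted p under 0.05. Among 28112 probes that varied at least 2-fold in both lines, the stage of the highest mean was 0 h for 29.6% in LP104 and 26.1% in LP106, 2 h for 20.4% and 22.5%, and 144 h for 14.6% and 17.4%. The lines shared that stage for 53% of these probes, where independent lists would share 17.6%. These shares depend on scaling: 0 h was highest for 21.3% and 23.9% with the median, 23.8% and 21.7% with quantiles, and 0.658% and 0.975% with spike-ins. With spike-ins 2 h was highest for 2.78% in LP104 and 5.66% in LP106, 120 h for 1.48% and 55.6%, and 144 h for 78.6% and 11%. The lines shared the stage for 49% of the probes with the median, where independent lists would share 14.7%, for 51.6% with quantiles (15.7%) and for 18.1% with spike-ins (10.5%).

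**Figure D2:**
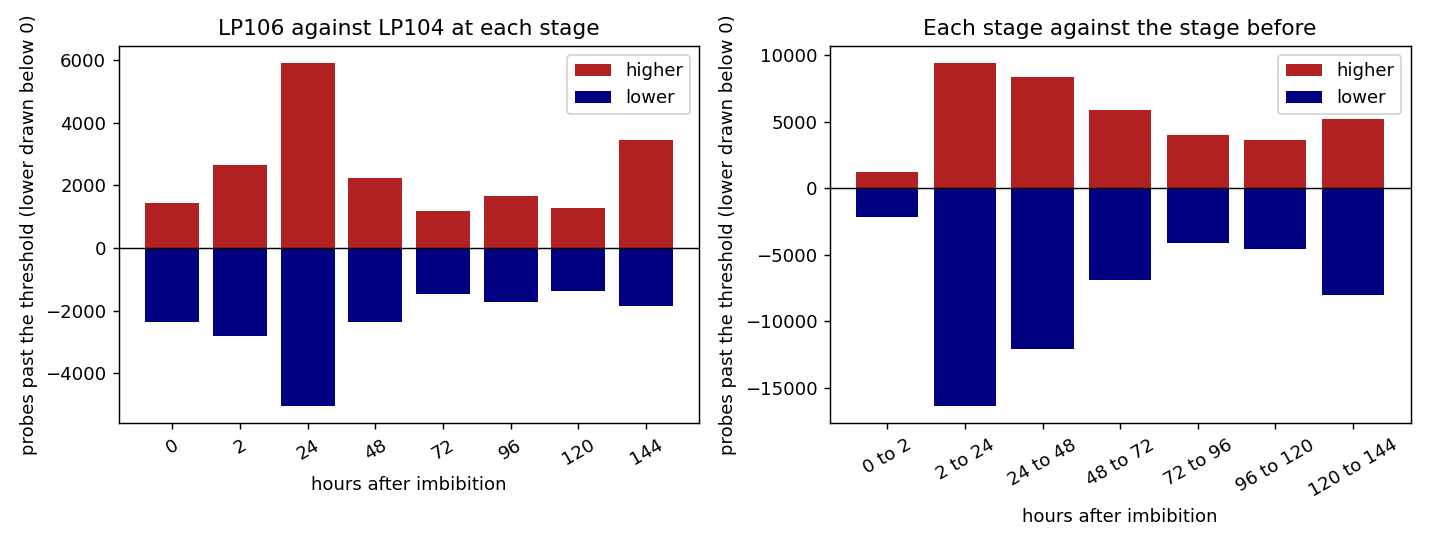
Probes past an adjusted p of 0.05, higher above 0 and lower below 0, for LP106 against LP104 at each stage (left) and for each stage against the one before (right); axes give hours after imbibition and numbers of probes. With 75th-percentile scaling the line comparison is highest at 24 h, with 5897 higher and 5044 lower, while with spike-ins it is highest at 144 h, and the step from 2 to 24 h has 9428 higher and 16396 lower.

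Detection changed with time. The flag for well above background is set before scaling, and the signal of whole arrays rose. Their log2 75th percentile was 5.857 in LP104 and 5.486 in LP106 at 0 h. It was 8.217 and 7.074 at 24 h, and 10.11 and 9.096 at 144 h. Gains in detection cannot be told apart from this rise. Probes not well above background on any 0 h array and above it on every array of a later stage numbered 4358 in LP104 and 2235 in LP106 at 24 h, 4338 and 5912 at 48 h, and 4965 and 5742 at 144 h. At 2 h 26 and 55 were gained in this way, and 147 and 303 were lost, that is above background on every 0 h array and on none at the later stage. At 144 h 336 and 707 were lost. Counts of the lines are not alike in kind, since 0 h had 3 LP104 arrays and 2 of LP106. The share of probes detected at 24 h was 58.7% ± 2.14 in LP104 and 49% ± 1.93 in LP106 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible, adjusted 0.8 over 8 stages). The 75th percentile of signal relative to spike-ins went from -5.80 ± 0.60 log2 units in LP104 and -5.74 ± 0.41 in LP106 at 0 h (SD, n = 3 and 2) to -1.45 ± 0.13 and -2.89 ± 0.32 at 144 h (SD, n = 3 each). In LP106 it was -2.17 ± 0.26 at 120 h (SD, n = 3), above its level at 144 h. At 24 h it was -3.37 ± 0.06 in LP104 and -4.58 ± 0.24 in LP106 (SD, n = 3 each; exact permutation p = 0.1, adjusted 0.4).

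**Figure D3:**
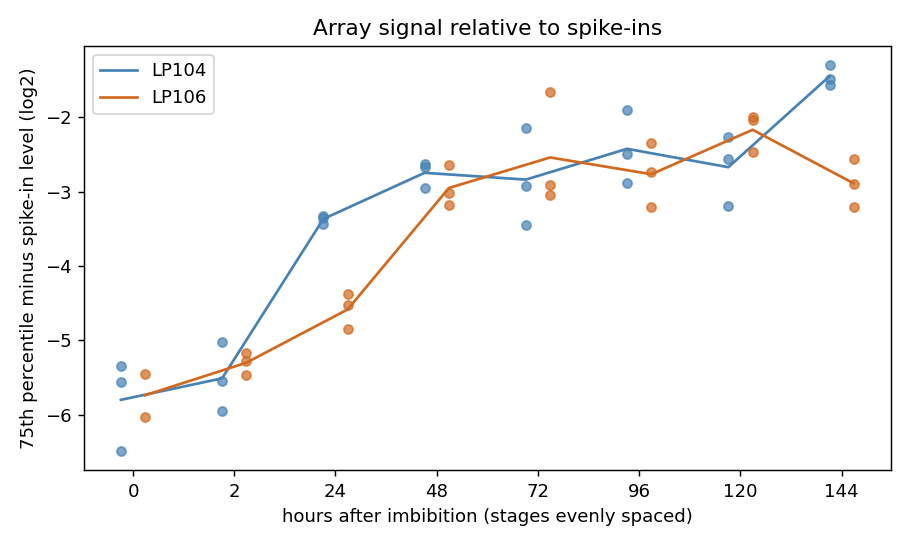
The 75th percentile of each array minus its spike-in level, in log2 units, against hours after imbibition; points are arrays and lines join the means of LP104 and LP106. LP106 minus LP104 is -1.22 at 24 h and -1.44 at 144 h, and 0.21 at 2 h, 0.30 at 72 h and 0.50 at 120 h.

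The lines were then compared at each stage. LP106 differed from LP104 at 3795 probes at 0 h (1424 higher, 2371 lower), 5438 at 2 h (2645 and 2793), 10941 at 24 h (5897 and 5044), 4614 at 48 h (2241 and 2373), 2634 at 72 h (1172 and 1462), 3392 at 96 h (1660 and 1732), 2631 at 120 h (1273 and 1358) and 5283 at 144 h (3442 and 1841). Directions depended on scaling at several stages. The share higher in LP106 at 24 h was 53.9%, against 32.3% with the median, 41% with quantiles and 1.98% with spike-ins. At 144 h it was 65.2%, against 50.1% with quantiles and 0.856% with spike-ins. At 2 h it was 48.6% against 32.7% with the median, and at 96 h 48.9% against 33.9% with the median and 24.3% with spike-ins. With spike-ins it was 27.7% at 48 h, 57.6% at 72 h and 69.5% at 120 h, against 48.6%, 44.5% and 48.4%. Within 1 slide, 6334 probes differed at 24 h (2 arrays against 3). Within single slides where 1 line had 1 array, the counts were 106 at 0 h, 0 at 2 h (limma; 3533 at an unadjusted p under 0.05), 397 at 48 h, 897 at 72 h, 1421 at 96 h, 717 at 120 h and 217 at 144 h. With slide as a block the count at 48 h was 2034. One LP104 array at 0 h carried signal at probes that mark LP106. Without it the 0 h count was 3475, and leaving out each 0 h array in turn gave 2565 to 3720. Over the alternatives the count ranged from 558 to 4822 at 0 h, 931 to 7158 at 2 h, 6154 to 21296 at 24 h, 1497 to 7216 at 48 h, 925 to 3978 at 72 h, 1344 to 7295 at 96 h, 1069 to 6402 at 120 h and 1402 to 27677 at 144 h. Without LP106 48 h replicate 3 the 48 h count was 2814. The stage with the most line differences was 24 h in 14 of 15 alternatives, and 144 h with spike-ins. The order of other stages was less stable. With array weights 3922 probes differed at 2 h and 6402 at 120 h, against 5438 and 2631 in the reported fit.

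Averaged over stages, 11219 of 33879 probes differed between lines, 6419 higher and 4800 lower in LP106, and 6924 of 15936 with the filter on all arrays. The share higher was 57.2%, against 41.6% with the median and 12.2% with spike-ins. A set of 609 probes passed the threshold with 1 sign at all 8 stages, 287 higher and 322 lower in LP106, with a median absolute difference of 1.97 log2 units. That set held 208 probes with spike-ins, 316 with the filter on all arrays, 360 with normexp and 378 on scan day 2. Detection separated the lines at 33 probes: 21 were well above background on all 24 LP104 arrays and no LP106 array, and 12 on all 23 LP106 arrays and no LP104 array. Their median lower bounds were 30.9-fold and 29.6-fold. CUST_2983_PI403524517, well above background on 23 of 23 LP106 and 3 of 24 LP104 arrays, was at least 522-fold higher in LP106 (limma adjusted p = 4.84e-23). CUST_2375_PI403524517, well above background on 24 of 24 LP104 and 4 of 23 LP106 arrays, was at least 530-fold higher in LP104 (limma adjusted p = 6.47e-24).

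The line by time interaction asked whether the lines changed differently, and 11081 probes passed. Under spike-in scaling 26020 did, and on scan day 2 alone 4632. The change from 0 h differed between lines at 4068 probes at 24 h and at 404 at 2 h.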

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

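The tests of slide row, of the 4 scalings, of the constant hybridisation difference and of the spike-in amount were chosen only after their results were seen. The change over time differed between the lines. By limma's moderated F-test of the 7 line differences in the change from 0 h, 11081 of 33879 probes passed an adjusted p of 0.05. By stage, the change from 0 h differed between lines for 404 probes at 2 h, 4068 at 24 h, 2194 at 48 h, 1371 at 72 h, 1729 at 96 h, 1993 at 120 h and 2300 at 144 h.

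The stage with the most line differences was 24 h, with 10941 probes, in the reported fit and in 14 of 15 alternatives; with spike-in scaling it was 144 h (27677 against 21296). All LP104 arrays of this stage lay in row 1 of their slides and all LP106 arrays in row 2. With a row term, whose size comes from the other stages, 9209 probes still passed. That argues against a row shift that is the same at all stages as the whole cause. A row shift of the 24 h arrays alone cannot be told apart from a line difference. A slide effect is argued against too, since the 5 arrays on 1 slide alone gave 6334. The part of scaling in the direction of the calls stays open. Of 5897 probes higher in LP106, 409 were higher under all 4 scalings, and 4758 of 5044 lower ones were lower, but spike-in scaling moves the median of all probes from 0.07 to -1.15, which fixes that outcome, so scaling and a line difference cannot be told apart for these directions. The 75th percentile relative to the spike-ins was lower in LP106 by a log2 difference of -1.22, and within 1 slide by -1.21; the percentile itself differed by -1.14, which argues against the amount of spike-in as the cause. At 144 h the same percentile differed by -1.01 with an SD of 0.888 in LP104, so there the amount of spike-in and a lower signal cannot be told apart, and a difference between the lines in RNA amount remains open and untested.

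The 609 probes (208 with spike-in scaling, 316 with the filter on all arrays, 360 with normexp, 378 on scan day 2) that differed with 1 sign at all 8 stages could reflect a sequence difference under the probe, which would give a constant log ratio. Among the 289 of them well above background on all arrays, 52.6% also had an interaction past the threshold, and 116 (40.1%) had one under all 4 scalings. That argues against a constant log ratio as the whole cause for those 116 probes. An interaction was also common among all probes well above background on every array, with 7697 of 15936, so it is not particular to this set. That count comes from a separate fit under the reported scaling, adjusted over those 15936 probes alone. It is not alike in kind to the 52.6% from the fit of all tested probes or to the 40.1% under all 4 scalings. A sequence difference whose log ratio varies was not tested. A sequence difference stays open for the rest of the 609, as probe sequences were not used here, and a difference in transcript level was not tested apart from it.

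Other splits of the arrays were counted for the line differences with 3 arrays per line, which leaves out 0 h, where LP106 had 2. The average line difference, the interaction and the changes over time were also split, and those that involve 0 h use these 2 arrays. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the highest count. The highest other counts were 498 against 5438 at 2 h, 32 against 10941 at 24 h, 729 against 4614 at 48 h, 2 against 2634 at 72 h, 0 against 3392 at 96 h, 0 against 2631 at 120 h and 40 against 5283 at 144 h. Each of these other splits mixes arrays of both lines. Part of the real line difference then counts as spread, so these counts do not measure what chance alone gives. For the average line difference and the interaction, line labels were drawn within stages, giving 100 splits with the real one. The highest other counts were 1135 against 11219 and 5753 against 11081, so a random labelling of the lines can be excluded at a share under 0.05. Such draws also turn a constant line difference into an interaction, so they do not test the interaction apart from it. They mix the lines within stages too, which turns part of the line difference into spread. Their counts for the average line difference therefore do not measure what chance alone gives. For each change over time, stage labels were drawn within lines, giving 40 splits with the real one. The real split had the highest count, a share under 0.05. Other splits can keep part of the real stage difference, so their counts do not measure what chance alone gives. The highest other counts there were 1171 against 3362 from 0 to 2 h, 22991 against 25356 from 0 to 24 h, 23230 against 27736 from 0 to 48 h, 26381 against 28204 from 0 to 72 h, 24111 against 28514 from 0 to 96 h, 23315 against 27984 from 0 to 120 h, 27552 against 28964 from 0 to 144 h, 21074 against 25824 from 2 to 24 h, 13905 against 20407 from 24 to 48 h, 8580 against 12795 from 48 to 72 h, 4918 against 8195 from 72 to 96 h, 3768 against 8176 from 96 to 120 h and 5300 against 13258 from 120 to 144 h.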

How the results depend on the processing

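The spike-in scaling, the slide row term, the fit on scan day 2, the set of probes past the threshold at all 8 stages, the 24 h position and the scalings of the peak stages were chosen after the data were seen. In the lists that follow, "lines at" is LP106 against LP104 at a stage, 2 hours give a stage change, and the all-stage set is the probes past the threshold with 1 sign at all 8 stages. Under quantile normalization, the trend and robust variance, scan day as a block, the series matrix values and slide row, every count stayed within 1.5 times of its reported value. The replicate numbers did not pair the arrays: 5 of 23 same-numbered pairs had a correlation of deviations over 0.1, the range being -0.198 to 0.326. With the replicate block, 10943 probes differed between lines at 24 h and every count stayed within 1.5 times. Counts that moved further were these. Median scaling gave 1779 (0 to 2 h). Normexp was planned on mean signals. The scanner values used here lack them, so it was run on median signals. It gave 1367 (lines at 0 h), 1623 (lines at 2 h), 18830 (lines at 24 h), 10254 (lines at 144 h), 393 (0 to 2 h), 360 (all-stage set) and -0.151 (24 h position). Without a filter on dim probes, which tests 53258 probes in place of 33879, there were 2075 (0 to 2 h), 40016 (0 to 24 h), 46068 (0 to 48 h), 46819 (0 to 72 h), 47303 (0 to 96 h), 46637 (0 to 120 h), 47099 (0 to 144 h), 42426 (2 to 24 h) and -0.252 (24 h position). The filter on all 47 arrays, which tests 15936 probes in place of 33879, gave 6154 (lines at 24 h), 2764 (lines at 48 h), 1571 (lines at 72 h), 2217 (lines at 96 h), 1516 (lines at 120 h), 6924 (line average), 12990 (0 to 24 h), 13800 (0 to 48 h), 13964 (0 to 72 h), 14073 (0 to 96 h), 13872 (0 to 120 h), 14175 (0 to 144 h), 13022 (2 to 24 h), 10910 (24 to 48 h), 7722 (48 to 72 h), 5170 (72 to 96 h), 7885 (120 to 144 h) and 316 (all-stage set). Array weights gave 1985 (lines at 0 h), 7216 (lines at 48 h), 3978 (lines at 72 h), 7295 (lines at 96 h), 6402 (lines at 120 h), 8665 (lines at 144 h), 872 (0 to 2 h), 13022 (72 to 96 h) and 13816 (96 to 120 h). Fits of only the groups compared, with fewer arrays for the spread, gave 558 (lines at 0 h), 1768 (lines at 2 h), 2130 (lines at 48 h), 1661 (lines at 72 h), 2168 (lines at 96 h) and 72 (0 to 2 h). Slide as a block gave 2034 (lines at 48 h) and 2933 (96 to 120 h). Spike-in scaling gave 572 (lines at 0 h), 931 (lines at 2 h), 21296 (lines at 24 h), 1497 (lines at 48 h), 925 (lines at 72 h), 1344 (lines at 96 h), 1069 (lines at 120 h), 27677 (lines at 144 h), 325 (0 to 2 h), 3814 (48 to 72 h), 2445 (72 to 96 h), 1754 (96 to 120 h), 5077 (120 to 144 h), 26020 (interaction), 208 (all-stage set) and -0.293 (24 h position). The 33 arrays of scan day 2 alone gave 2526 (lines at 48 h), 1475 (lines at 72 h), 1806 (lines at 96 h), 1506 (lines at 120 h), 1402 (lines at 144 h), 964 (0 to 2 h), 7409 (48 to 72 h), 4622 (72 to 96 h), 5219 (96 to 120 h), 4632 (interaction) and 378 (all-stage set). Where the number of probes or arrays tested differed, counts could move for that reason alone. Elsewhere the cause was not tested. The reported fit gives each probe 1 spread shared by all groups. Estimated array weights, lower for noisier arrays, were 0.4443 to 0.9477 at 0 and 2 h and 0.4492 to 3.423 at later stages. The shared spread may therefore be too small for 0 and 2 h, and counts of early and late stages may not be alike in kind. Leaving out 1 array at a time moved a few results. The change from 0 to 2 h ranged over 2236 to 3579, the lowest without LP106 0 h replicate 1. The line difference at 48 h ranged over 2814 to 5437, the lowest without LP106 48 h replicate 3. The 24 h position ranged over -0.039 to 0.0113 and changed sign without LP106 24 h replicate 1 (0.0032) or LP104 48 h replicate 2 (0.0113). The other counts stayed within 1.5 times, and the 4 named probes kept direction and threshold wherever they were tested. The gene list alternatives were not run, since no probe had a gene name here. Signal over background was lowest early: 43.7% of probes in LP104 and 44.3% in LP106 were well above background at 0 h, and 41.7% and 42.5% at 2 h, against 59.7% and 56.5% at 144 h.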

Other observations

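Except the comparison of brighter with dimmer marker probes, the tests here were chosen after the result was seen.

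LP104 0 h replicate 1 carried signal at probes that mark LP106. Marker probes were taken from the other stages as those well above background on all LP106 arrays and on at most 10% of LP104 arrays. Of 44 such probes, 15 were well above background on this array (34.1%), against 1 on replicate 2 and 0 on replicate 3, and at most 15.9% on any other array of the series. All 44 LP104 marker probes (100%) were above background on it, which argues against a mislabelled array. Of the 22 LP106 markers that were brighter in LP106 at 0 h, 15 (68.2%) were on, and 0 of the 22 dimmer ones (two-sided Fisher's exact test p = 1.48e-06). Their levels lay between -3.95 and -2.57 log2 units relative to LP106 at 0 h, with a median of -3.33. A small share of LP106 material in this sample is a candidate explanation, and the step at which it might have entered was not tested. This array also had the highest signal of the 0 h arrays. Its log2 75th percentile was 6.385, against 5.56 and 5.626 in replicates 2 and 3, with 48.16% of probes detected against 40.96% and 42.1%. A higher signal could also bring the brighter markers above background first, so the flags do not tell the 2 apart. Without this array 3475 probes differed between lines at 0 h in place of 3795, and 2322 changed from 0 to 2 h in place of 3362. These drops are not particular to it. Leaving out 1 array at a time gave 2565 to 3720 for the lines at 0 h and 2236 to 3579 for 0 to 2 h.

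A further hypothesis was that LP106 runs behind LP104 at 24 h. The position of each array between the stage before and the stage after was computed for 6 stages on 2 axes, 12 comparisons in all, each with 3 arrays per line and an exact two-sided permutation p of at least 0.1. On each line's own axis from 2 to 48 h, the one computed first, LP106 differed from LP104 at 24 h by -0.0182 with an SD of 0.0366. Of 7 other settings, 4 gave a difference within that SD: -0.00244 (quantiles), -0.00524 (series matrix), -0.02 (median) and -0.0265 (filter on all arrays). The other 3 gave -0.151 (normexp), -0.252 (no filter on dim probes) and -0.293 (spike-in scaling), beyond it. The sign turned without LP106 24 h replicate 1 (0.0032) or LP104 48 h replicate 2 (0.0113), so this measure settles neither a lag nor its absence. On the axis of both lines' mean it differed by -0.125 with an SD of 0.0377. Shifts of over 1 SD in the same direction occurred on that axis at 5 of the 6 stages, so a lag at 24 h and a general offset between the lines cannot be told apart. On the own axes, wider gaps than at 24 h were measured at 48 h (-0.0976, SD 0.0836) and 120 h (-0.23, SD 0.0278). In the other direction they were wider at 72 h (0.0377, SD 0.0812) and 96 h (0.0413, SD 0.047).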
